A study of Xenopus laevis with 4 samples.

How the data were processed

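Gene expression was measured in explants of the animal cap, the ectoderm at the roof of the Xenopus laevis blastula, on 4 single-colour Affymetrix Xenopus arrays. Per the labels' protocols, chordin mRNA was injected at 25 pg per cell into every blastomere at the 4-cell stage, and uninjected embryos were handled alike apart from the injection. Embryos were raised at 22 °C and then at 15 °C, caps were cut at stage 8 and kept for 3 h, and labelled cRNA was made from 250 ng of total RNA. The groups, taken from the sample titles, were 2 uninjected and 2 chordin samples, each called a biological replicate. No sample injected with a control mRNA was analysed here, so injection and chordin are one contrast. The labels do not say whether the samples came from separate batches of embryos, so the p-values measure only the spread between these samples.

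The deposited values are log2 values made by the authors with RMA, per the submitters' processing notes, which give no version. In the deposited log2 table, all 32635 probe sets had a median of 0 over the 4 arrays, within 1e-06, so each probe set had been centred on its own median. Differences between arrays are kept by that step and absolute levels are lost. The scale is taken as log2 because RMA gives it, and the direction follows from the sample that heads each column. The medians of the columns were -0.01 and 0.01 for uninjected samples 1 and 2, and 0.01 and 0.00014 for chordin samples 1 and 2. The software and the source of the centring are not given in the sources used here. No further normalization was applied.

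The 160 control probe sets were left out, and 32475 were tested. Genes were named from the platform annotation, whose Entrez identifiers were matched to a table of the Xenopus_laevis_v10.1 assembly. This match was made for 15384 of the tested probe sets and updated 1 symbol. A single symbol was given for 15495 tested probe sets and several for 279, while 16701 were unnamed here. No gene was named from a probe set with several symbols. The suffixes .L and .S mark the homeologs, the copies of a gene on the long and short chromosome sets, which were treated as separate genes. Array probes can cross-hybridise between homeologs, and this was not tested.

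Chordin was compared with uninjected samples in R 4.3.3 with limma 3.58.1, using lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. One fit covered the probe sets and another the 11303 genes with a symbol, each gene being the mean of its probe sets (2702 genes had more than 1). Values given for genes and all adjusted p-values of genes come from this second fit unless another setting is named. A gene said not to pass did not pass in this main fit. A count without a variance model took the probe sets whose nearest arrays of the 2 groups lay at least 1 log2 unit apart, and the same count was made for the other splits of the 4 arrays. The number of arrays, 2 per group, limits the precision.

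The 19 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Each list was set against all other genes with camera in limma, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 19 lists. Beside it, camera with an estimated correlation and fry were run. Members were matched by symbol, including older names. The named genes were chrd and tent5a, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap (filled by the smallest p where fewer passed), and up to 4 members of each list, first those past the threshold by size of change and then by smallest p. Members of the lists that the report names beyond this rule, such as bmp4, sox2, krt12 and the eye field genes, were chosen after their values were seen.

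The centring forced departures from this plan. The brightest probe set of a gene could not be picked, so the mean of a gene's probe sets, first meant as a second setting, was used throughout. The requirement that a named gene reach the median level was dropped for the same reason. Alternatives that were run covered quantile normalization, centring each array on its median, the replicate number as a block, leaving out each array in turn, other thresholds and other list tests. A robust prior, list tests on single probe sets, and lists without members shared with the BMP target list were added after seeing the data.

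The tests were tested on simulated data with the spread of the real fits and 200 changed features. Over 32475 simulated probe sets, changes of 1, 2, 3 and 5 log2 units were recovered in 0%, 44.0%, 86.0% and 94.0% of cases, with 4 false calls. Over 11303 simulated genes the shares were 2.0%, 70.0%, 80.0% and 100%, with 5 false calls. In simulated gene lists, 0 of 20 unchanged lists were called and the 1 shifted list was. Genes were simulated as independent, without a difference between replicate numbers. The simulation therefore does not show how often camera calls unchanged lists of correlated genes.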

Results

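The transcripts of 4 samples of animal cap explants were measured, 2 from uninjected embryos and 2 from embryos injected with mRNA of chordin, a secreted antagonist of bone morphogenetic proteins (BMPs). Per the series' stated design, the comparison was made to screen for genes involved in neural induction. Animal caps left alone form epidermis, and blocking BMP signals turns them towards neural tissue. Values are log2 expression relative to each probe set's median over the 4 arrays, averaged over the probe sets of a gene, so changes are measured and levels are not.

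In chordin caps many target genes of BMP signalling fell and a small set of early neural genes rose. Among genes that passed, the largest fall was in szl.L, which encodes Sizzled, a secreted feedback inhibitor made on the ventral side of the embryo. It lay at 4.12 ± 0.25 (SD, n = 2) in uninjected and -3.96 ± 0.03 (SD, n = 2) in chordin caps, a log2 change of -8.08 ± 0.18 (SE), 270.4-fold lower, with an adjusted p of 0.00421 (log2 change of -7.26 after quantile normalization). The largest rise among them was in foxd4l1.1.S, which encodes a forkhead factor of the early neural plate. It went from -2.56 ± 0.17 (SD, n = 2) to 3.08 ± 0.91 (SD, n = 2), a log2 change of 5.65 ± 0.45 (SE), 50.1-fold, with an adjusted p of 0.0416. The log2 change was 5.01 without chordin sample 1, 6.29 without chordin sample 2 and 6.44 after quantile normalization. In all, 34 of 11303 genes passed the threshold, 5 higher and 29 lower in chordin caps. Of these, 27 belonged to a list fixed beforehand.

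Among the 10 named falls, szl.S fell by 7.84 ± 0.25 (SE) on the log2 scale and gata2.L, a transcription factor gene of ventral ectoderm and blood, changed by -6.75 ± 0.36 (SE). The forkhead gene foxi4.2.L fell by 5.75 ± 0.18 (SE), and bambi.L, which encodes a decoy receptor that dampens BMP signals, fell by 5.26 ± 0.22 (SE). The homeobox genes dlx3.S, ventx1.1.S and msx1.S had changes of -5.08, -4.82 and -4.75. The Notch ligand gene dlc.L fell by 4.46 and the T-box gene tbx2.L fell by 4.44. Adjusted p-values of these 10 genes lay between 0.00421 (szl.L) and 0.0287 (dlx3.S).

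The other rises that passed were hes5.2.L, a repressor gene of the Hes family, by 3.90 ± 0.27 (SE, adjusted p = 0.0305), and fzd4.S, a Wnt receptor gene, by 2.82 ± 0.19 (SE, adjusted p = 0.0282). They were joined by cyp26a1.S, whose product degrades retinoic acid, with 2.58 ± 0.22 (SE, adjusted p = 0.0498), and foxd4l1.2.L with 1.74 ± 0.14 (SE, adjusted p = 0.0422). The rise of cyp26a1.S did not pass with arrays centred on their medians (adjusted p = 0.0512), nor did those of cyp26a1.S (0.0538) and hes5.2.L (0.0648) after quantile normalization. A further 5 genes, next by p, did not pass in the main fit (adjusted p from 0.0526 for tsc22d3.L to 0.0719 for cyp26a1.L). They included tsc22d3.L with a log2 change of 1.89, the head gene otx1.L with 3.41, hpgds.L with 1.43 and cyp26a1.L with 2.78. The other was lrat.L, which encodes a retinol-esterifying enzyme, with 1.53. All 5 passed with the replicate number as a block (adjusted p from 0.000935 for otx1.L to 0.00927 for hpgds.L).

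**Figure D1:**
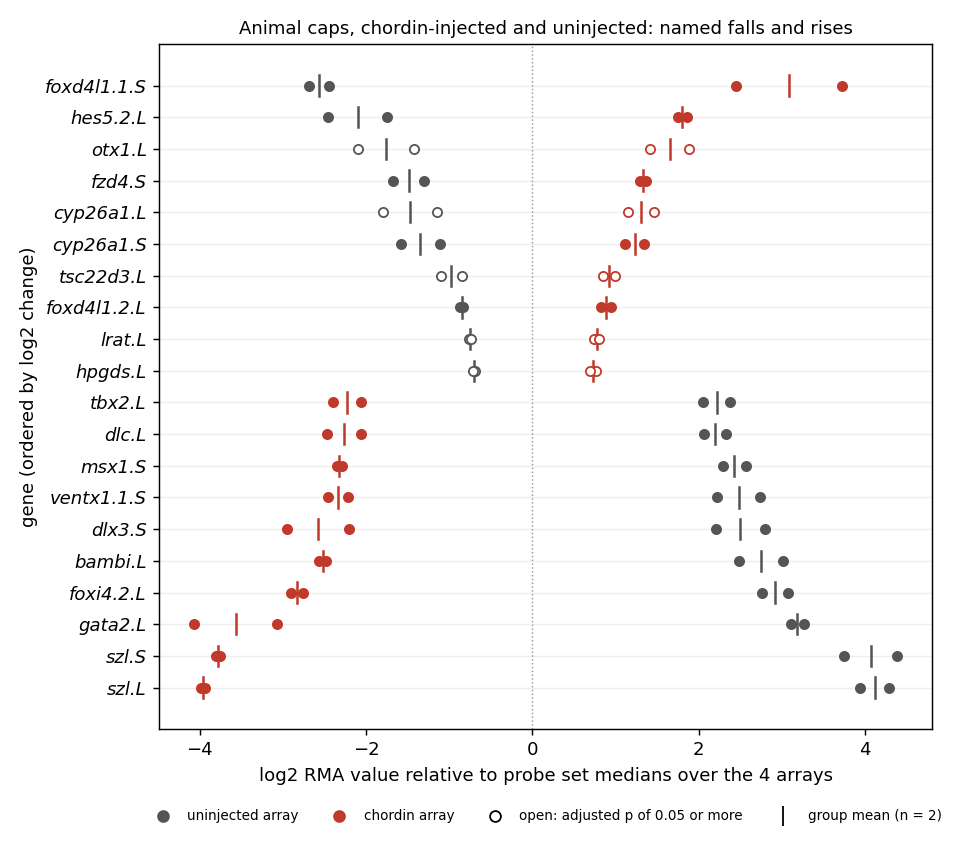
Each point is 1 array's log2 value relative to the probe set medians over the 4 arrays (x axis), for the 10 named falls and 10 named rises (y axis); grey points are uninjected and red points chordin arrays, bars are group means (n = 2), and open points mark genes that did not pass. By the rule that chose these genes, the arrays of the groups do not overlap for any of them, and the change runs from -8.08 in szl.L to 5.65 in foxd4l1.1.S.

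Over probe sets rather than genes, 50 of 32475 passed, 5 higher and 45 lower, and 17 of the 50 have no gene name here. The counts of called probe sets and genes changed with the array left out, and such fits take their spread from the group that keeps 2 arrays. All 34 called genes kept their sign in each of these fits. This outcome was fixed beforehand, since the arrays of the groups do not overlap for any of them. Without uninjected sample 1, limma called 0 probe sets (1659 had an unadjusted p under 0.05) and 2 genes, szl.L and szl.S. Without uninjected sample 2 it called 0 probe sets (2151 had an unadjusted p under 0.05) and 5 genes, szl.L, szl.S, foxi4.2.L, bambi.L and, higher, otx2.L. Without chordin sample 1 it called 15 probe sets and 25 genes. By distance alone, 342 probe sets had the arrays of the groups at least 2-fold apart, 118 higher and 224 lower in chordin caps. Splitting the arrays by replicate number instead gave 613 such probe sets, and the third split gave 0. Control probe sets gave 0 in all 3 splits. On the probe sets for the ends of the GAPDH transcript, the 3' minus 5' difference in centred log2 value was 0.09 and 0.48 in the uninjected arrays. It was -0.09 and -0.33 in the chordin arrays, so the groups did not overlap. For actin it was -0.35 and 0.17 against 0.08 and 0.10, which overlap. Of 2 against 2 groupings, 33.3% do not overlap by chance. These centred values compare arrays and do not show how intact the RNA was.

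BMP target genes moved down as a group by camera (adjusted p = 2.15e-74), which did not pass with an estimated correlation (adjusted p = 0.0606) and had an adjusted p of 0.0075 by fry. All 36 measured members had lower values in chordin caps, with a median log2 change of -3.37. Of these, 17 fell, 0 rose and 19 did not pass, while 33 fell when adjusted over the list alone. The arrays of the groups lay at least 2-fold apart in 27. Besides szl.L, szl.S, gata2.L and bambi.L, the falls included msx1.L (21.2-fold lower), ventx2.1.S (18.3-fold lower) and the inhibitor of differentiation genes id2.S and id2.L (log2 changes of -3.28 and -2.77). The ligand genes bmp4.S and bmp4.L, at -0.72 ± 0.21 (SE) and -0.40 ± 0.28 (SE), did not pass (adjusted p = 0.572 and 0.927). The 7 probe sets of ventx1.1.L disagreed, with log2 changes from -4.05 to 0.28 behind the gene's mean of -0.62.

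Early neural genes moved up as a group, with a median log2 change of 0.67 over 47 measured members and a camera adjusted p of 1.19e-09, against an adjusted p of 0.273 with an estimated correlation and 0.0767 by fry. Of these members, 33 lay higher and 14 lower. Over all genes foxd4l1.1.S, hes5.2.L and foxd4l1.2.L rose, 0 fell and 44 did not pass. Adjusted over the list alone, 18 rose and 1, the tubulin gene tubb2b.S, fell. Next by p was gmnn.L, which encodes geminin, with a log2 change of 1.69 ± 0.18 (SE, adjusted p = 0.0831). The neural plate genes zic1.S, zic2.S, sox3.S and sox11.S, named after their values were seen, lay 2.26, 1.60, 1.22 and 1.73 higher without passing over all genes. The pan-neural gene sox2.L had a log2 change of 1.35 ± 0.47 (SE, adjusted p = 0.691).

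Genes of the anterior neural plate and eye field had a median of 0.07 and a camera adjusted p of 0.00179, and an adjusted p of 0.419 with an estimated correlation. The median was 0.19 without uninjected sample 2 and 0.15 without chordin sample 2. Of 33 measured members 22 lay higher and 11 lower. Adjusted over the list alone 8 members were higher and 0 lower, and 0 of 33 passed over all genes in the main fit. The 4 named members, all genes of the forebrain or its precursors, were otx1.L at 3.41 ± 0.31 (SE), otx2.L at 4.62 ± 0.46 (SE), crx.L at 4.48 ± 0.50 (SE) and hesx1.S at 1.76 ± 0.24 (SE), with adjusted p-values from 0.0536 to 0.133. These 4 passed with the replicate number as a block (adjusted p from 0.000935 for otx1.L to 0.0117 for hesx1.S). The eye field genes rax.L, pax6.L and six3.L lay at 0.35, -0.44 and 0.06 and did not pass in the main fit. Posterior neural and Hox genes were not called (adjusted p = 0.492, median 0.03, 0 of 18 passing). Only meis3.S with 1.33 and gbx2.2.L with 1.35 rose when adjusted over the list alone. Without passing in the main fit, cdx2.L lay at -1.45 (-2.26 without chordin sample 1 and -0.64 without chordin sample 2) and meis3.L at 0.87 (0.51 without uninjected sample 1). With the replicate number as a block, meis3.S, gbx2.2.L and cdx2.L passed (adjusted p = 0.0149, 0.0227 and 0.0363) and meis3.L did not (0.0672).

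Epidermal and non-neural ectoderm genes moved down, with a median of -0.32 and a camera adjusted p of 8.89e-13, against an adjusted p of 0.12 with an estimated correlation. Among 41 measured members 31 lay lower and 10 higher, and 14 fell when adjusted over the list alone. Over all genes 3 fell, 0 rose and 38 did not pass. The falls were in foxi4.2.L and foxi4.2.S, with log2 changes of -5.75 and -2.68, and in the homeobox gene dlx2.S, with -3.69. For foxi4.2.S, the 4 probe sets changed by -4.42 to -0.37, and the fall of the gene did not pass after quantile normalization (adjusted p = 0.064). The homeolog dlx2.L lay at -1.45 (adjusted p = 0.0719). The epidermal keratin genes krt12.4.S and krt12.5.S lay at -3.81 ± 0.61 (SE) and -5.28 ± 1.13 (SE) without passing over all genes.

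Genes of the specialised skin cells (multiciliated cells, ionocytes and secretory cells) were lower in 21 of 24 members, with a median of -0.26 and a camera adjusted p of 3.55e-07, and an adjusted p of 0.178 with an estimated correlation. Only ubp1.L passed, with a fall by 1.96 ± 0.15 (SE), but not after quantile normalization (adjusted p = 0.0538). The ionocyte regulator gene foxi1.L lay at -2.73 ± 0.44 (SE), the Notch ligand gene dll1.L at -2.32 ± 0.44 (SE) and the ciliary regulator gene rfx2.S at -0.77 ± 0.17 (SE). When adjusted over the list alone, 6 fell and 1, the carbonic anhydrase gene ca12.L, rose.

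In the list of preplacodal and neural crest genes, 3 of 25 fell, msx1.S with a log2 change of -4.75, msx1.L (21.2-fold lower) and sox8.L with a log2 change of -2.42. The homeobox gene dlx5.L lay at -4.07 ± 0.36 (SE, adjusted p = 0.053). The neural crest genes foxd3.L and foxd3.S, chosen after their values were seen, lay at 2.07 ± 0.28 (SE) and 2.89 ± 0.71 (SE). These 2 rose and 6 others fell when adjusted over the list alone. In this list 14 members lay lower and 11 higher. The list was called lower (adjusted p = 0.00499), with an adjusted p of 0.344 under an estimated correlation. It was not called without chordin sample 2 (0.0605), nor, in an alternative added after seeing the data, without the 3 members it shares with the BMP target list (0.577).

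The list of pluripotency and early zygotic genes was lower, with a median of -0.24 over 28 members and a camera adjusted p of 2.44e-09, and an adjusted p of 0.178 with an estimated correlation. Its median was -0.43 without uninjected sample 1, -0.48 without chordin sample 2, -0.10 over single probe sets and -0.07 without the members it shares with the BMP target list (adjusted p = 0.0137), the last 2 added after seeing the data. It had 3 falls, in ventx1.1.S, ventx2.1.S and ventx1.2.S (log2 change of -3.97, adjusted p = 0.0538 after quantile normalization), which belong to the BMP target list too. The Krüppel-like factor gene klf17.1.S lay at -2.70 ± 0.24 (SE, adjusted p = 0.0536). It passed after quantile normalization (adjusted p = 0.0227) and with the replicate number as a block (0.00803). In all, 19 members lay lower and 9 higher, and 11 fell when adjusted over the list alone. Components of the BMP and nodal pathways had 0 of 33 past the threshold and 4 lower when adjusted over the list alone. These were the ligand gene bmp7.1.L at -2.85 ± 0.34 (SE), twsg1.S at -1.06, smad9.S at -1.76 and the receptor gene acvr1.L at -0.78. The median was -0.14 (-0.29 without uninjected sample 1), with a camera adjusted p of 5.57e-05, and an adjusted p of 0.178 with an estimated correlation. Of the 33 members, 24 lay lower and 9 higher.

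Cement gland and hatching gland genes, 9 in all, had 0 past the threshold and a median of -0.76, but a mean of 0.02. Members differed in direction, with crx.L and crx.S at 4.48 and 2.37 against has1.S at -0.78 and the cement gland gene ag1.S at -0.84 (-0.54 without uninjected sample 1). Of these, crx.L and crx.S rose and has1.S fell when adjusted over the list alone. Camera called the list lower (adjusted p = 0.0465), which became 0.419 with an estimated correlation, 0.0512 after quantile normalization and 0.0561 with arrays centred on their medians. It was 0.241 without uninjected sample 1, 0.176 without chordin sample 1 and 0.578 over single probe sets (median -0.45), an alternative added after seeing the data.

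**Figure D2:**
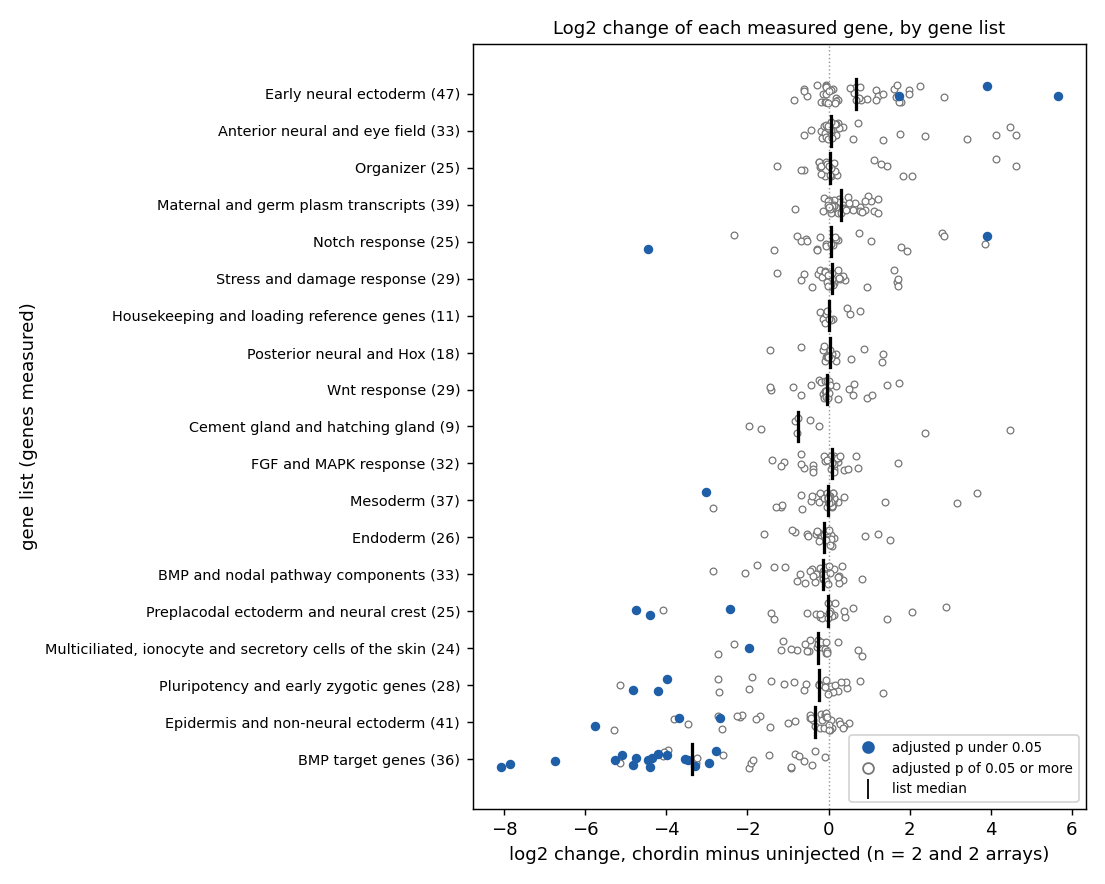
Each point is the log2 change of 1 gene, chordin minus uninjected (x axis, n = 2 and 2 arrays), in each of 19 gene lists (y axis, with the number measured); filled points passed the threshold and black bars are list medians. The BMP target list lies apart from the rest with a median of -3.37, and the other list medians lie between -0.76 and 0.67.

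Notch response genes moved in both directions. The ligand gene dlc.L fell by 4.46 and hes5.2.L rose by 3.90, while hes1.L at 1.94 ± 0.23 (SE) and hes4.L at -1.35 ± 0.17 (SE) did not pass in the main fit. With the replicate number as a block, hes1.L (adjusted p = 0.0159) and hes4.L (0.0116) passed. In this list 7 of 25 rose and 5 fell when adjusted over the list alone, and it was not called (adjusted p = 0.94). Wnt response genes were not called either (adjusted p = 0.94, 0 of 29 passing), and their median of -0.04 and mean of 0.05 differ in sign. The genes dkk1.S (1.44), axin2.L (0.95), ccnd1.S (1.07) and sfrp2.S (1.75) rose and myc.L (-1.43) fell when adjusted over the list alone. FGF and MAPK response genes had 0 of 32 passing by either adjustment in the main fit, a median of 0.09, a mean of -0.02 and an adjusted p of 0.703. Their named members were fgfr4.S at -1.09, fgfr4.L at -1.40, dusp1.S at 1.72 (1.13 without chordin sample 1) and flrt3.S at -1.16 (-0.60 without uninjected sample 1). With the replicate number as a block, fgfr4.S (adjusted p = 0.0386), fgfr4.L (0.0198) and dusp1.S (0.0309) passed and flrt3.S did not (0.141).

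Markers of other tissues that a dissected cap could hold were examined too. Of 37 mesoderm genes, foxf1.L, a gene of lateral and ventral mesoderm, fell by 3.03 ± 0.19 (SE), but did not pass after quantile normalization (adjusted p = 0.0554). Its homeolog foxf1.S at -2.86, mespa.S at -1.17 and the apelin receptor gene aplnr.L at 3.66 ± 0.53 (SE) did not pass, and adjusted over the list alone 3 rose (aplnr.L, aplnr.S and eomes.S) and 4 fell (foxf1.L, foxf1.S, mespa.S and fgf3.L). The mesoderm list had an adjusted p of 0.0594 and was called lower without uninjected sample 1 (0.00425) and without chordin sample 1 (0.00968), but without uninjected sample 2 it had a median of 0.08 (0.383) and without chordin sample 2 one of 0.04 (0.912). Of 26 endoderm genes 0 passed by either adjustment, with a2m.S at 1.52, gata4.S at -0.82, vegt.L at 1.23 and vegt.S at 0.90. Using the replicate number as a block, the mesoderm and endoderm lists were both called lower (camera adjusted p = 0.0361 each). In the main setting the endoderm list had an adjusted p of 0.0549 and a median of -0.10. Its adjusted p was 0.00425 without uninjected sample 1, 0.0463 over single probe sets (added after seeing the data), 0.585 without uninjected sample 2 (median 0.03) and 0.307 without chordin sample 2 (median -0.06). Organizer genes, 25 in all, had 0 past the threshold and an adjusted p of 0.492. By the adjustment over the list alone, otx2.L, otx2.S, the Wnt inhibitor gene dkk1.S (1.44), chrd.1.S and admp.S rose and not.L (-1.27) fell. The organizer gene gsc.L lay at 0.15 ± 0.16 (SE).

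Maternal and germ plasm transcripts were called higher (camera adjusted p = 4.14e-05, and an adjusted p of 0.344 with an estimated correlation), with 34 of 39 above the uninjected value and a median of 0.30 (0.19 without chordin sample 1), but 0 passed by either adjustment. The GAPDH 3' minus 5' difference of the centred values lay at -0.09 and -0.33 in the same chordin and 0.09 and 0.48 in the uninjected arrays. Named members were vegt.L at 1.23 ± 0.27 (SE), vegt.S at 0.90, ccnb1.S at 1.12 and ccnb2.L, which went the other way at -0.82. The list of stress and damage genes was not called (adjusted p = 0.637, median 0.08, 0 of 29 passing). Adjusted over the list alone, the cyclin gene ccng1.S at 1.68 ± 0.19 (SE) rose and gadd45a.S at -1.28 ± 0.16 (SE) fell, and sesn1.L lay at 1.60 and ccng1.L at 1.72 (1.06 without chordin sample 1). Housekeeping genes had a median of 0.01 and an adjusted p of 0.723, with 0 of 11 passing by either adjustment. The smallest p among them was that of tbp.L, at 0.77 ± 0.19 (SE), followed by tbp.S at 0.52, hprt1.L at 0.45 and slc35b1.L at -0.20, and without uninjected sample 1 these 3 lay at 0.24, 0.15 and -0.11.

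The injected gene and the gene in the series title did not pass in the main fit. When the replicate number was a block, chrd.1.S passed (adjusted p = 0.0275) and tent5a.L did not (0.0753). The probe set for chrd.1.S read -0.45 and -0.54 in the uninjected and 0.82 and 0.45 in the chordin arrays, a log2 change of 1.13 ± 0.19 (SE) with an adjusted p of 0.322 over all probe sets. Whether that probe set lies in the injected mRNA is not known, so it does not check the labels. For tent5a.L, once called fam46a, one probe set read -0.47 and -0.57 in the uninjected and 1.83 and 0.47 in the chordin arrays, a log2 change of 1.67 ± 0.47 (SE, adjusted p = 0.673). The other read 0.01 and -0.86 against 1.55 and -0.01, a change of 1.20 ± 0.61 (SE, adjusted p = 0.924). On both probe sets the change rested more on chordin sample 1 than on chordin sample 2, and the gene's mean change was 0.71 without chordin sample 1 and 2.16 without chordin sample 2.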

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

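Against 50 probe sets and 34 genes called in the main setting, adjusted p under 0.10 gave 92 probe sets, and the range on leaving out 1 array was 0 to 49 probe sets and 2 to 36 genes. In those fits the lone array is assumed to vary like the other group, and fewer arrays remain. Of the 34 genes, 27 were still called after quantile normalization, 33 with arrays centred on their medians and 33 with a robust prior (an alternative added after seeing the data). The count of probe sets 2-fold apart was 341 to 356 under other scalings, and 718 for a 1.5-fold gap.

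The number of lists called went from 10 to 0 with an estimated correlation and to 4 by fry, and lay between 8 and 12 in the other settings. For BMP target genes (median -3.37) the adjusted p was 0.0606 with an estimated correlation. For early neural genes (median 0.67) it was 0.273 with an estimated correlation and 0.0767 by fry. Both lists were called under every other setting run. The 2 camera runs used the same values, lists and design and differ only in whether the inter-gene correlation was fixed at 0.01 or estimated. The loss of calls between them therefore comes from this setting. Why fry gave fewer calls was not tested. Over the other 17 lists, 160 results were the same, 21 no longer passed, 6 newly passed and 0 with a call in either setting turned the direction given by the test. In 11 of the results counted as the same, a list called in neither setting turned, 5 of them for Wnt response, which is lower by camera and higher by fry. List medians near 0 changed sign in 13 results, 1 of them called, the preplacodal list without uninjected sample 2 (median 0.01, adjusted p = 0.0323, still lower by camera). For single named genes, 529 results were the same, 62 no longer passed and 41 newly passed, of which 36 came with the replicate block.

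Samples of the 2 groups share replicate numbers, but the labels do not say that a number marks a shared batch. The values followed the number in both groups, with 613 probe sets at least 2-fold apart by number and 0 in the third split. What the numbers mark is not known. The main fit, fixed beforehand without a block, counts this difference as spread within the groups. Across probe sets, the difference between samples 1 and 2 correlated between the groups (r = 0.69; genes are not independent replicates). With the replicate number as a block, 507 probe sets (194 higher, 313 lower), 212 genes and 12 lists were called. All 34 called genes were among these 212. Named genes newly called included chrd.1.S, otx1.L, otx2.L, crx.L and hesx1.S, and the lists newly called were mesoderm and endoderm, both lower.

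Filters on dim probe sets, a trend of variance with level and the brightest probe set of a gene were not run, since the deposited values hold no levels. Signal over background is unknown for the same reason.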

Other observations

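The tests on replicate numbers and on vegetal cells in this part, and the p53 values with single arrays left out, were chosen after the results were seen. The lists of other p53 target genes and other maternal transcripts were written before the values of their genes were seen.

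Outside the 19 lists, 64 named genes had the arrays of the groups at least 2-fold apart, 25 higher and 39 lower in chordin caps. The 7 of the 34 called genes that no list holds include hs3st1.L, a heparan sulfate sulfotransferase gene, which fell by 3.40 ± 0.14 (SE), gfpt2.L, an enzyme gene of the hexosamine pathway, which fell by 3.66 ± 0.25 (SE), and the signal gene nodal.L, which fell by 2.93 ± 0.14 (SE). The others were kcnk5.S, a potassium channel gene, and has-rs.S, lower by 2.20 and 2.21, with fzd4.S and cyp26a1.S. Further genes showed large changes in both homeologs without passing. For trim29.S and trim29.L the log2 changes were -4.23 ± 0.42 (SE) and -4.32 ± 0.68 (SE), and for lmo4.2.S and lmo4.2.L -2.65 ± 0.31 (SE) and -1.73 ± 0.23 (SE). Adjusted p-values lay between 0.0719 (trim29.S) and 0.203 (trim29.L). These genes were chosen after their values were seen.

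Samples numbered 1 differed from samples numbered 2 in both groups. For 613 probe sets the numbers lay at least 2-fold apart, more than the 342 for chordin, and for asmtl.L both samples 1 lay above both samples 2 with a mean difference of 133-fold. If the transcripts differed, a second separate probe set of the same gene should share the change, defined as the same sign and at least 50% of the size. This held for 18 of 83 genes, 21.7% (95% exact binomial interval 13.4% to 32.1%), against 24 of 40 genes, 60.0% (43.3% to 75.1%), for the chordin change (Fisher's exact test, two-sided, p = 4.32e-05). The upper end of 32.1% lay under the lower end for the chordin change, which was taken over another set of genes. Both intervals and the p count genes from the same arrays, which are not independent replicates. For these 83 genes the low share argues against a difference in stage or cell make-up as the whole cause. Of the 19 lists, 0 differed between the numbers by camera (smallest adjusted p = 0.525). No list was written to mark stage, so this last result does not decide on stage. Sequence variants of different parents under single probe sets may explain the low share, but other faults of single probe sets stay open.

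The hypothesis that injection brought a p53 response was tested because ccng1.S, ccng1.L, cdkn1a.L and sesn1.L lay higher in chordin caps. Their log2 changes were 1.68, 1.72, 1.72 and 1.60, and none of them passed in the main fit. In the fit with the replicate number as a block, ccng1.S (adjusted p = 0.0159) and sesn1.L (0.0375) passed and ccng1.L did not (0.0779). Among 29 measured other p53 target genes, 21 lay higher, with a median log2 change of 0.24 (95% bootstrap interval 0.09 to 0.35). The bootstrap drew genes of a list, so the intervals here and in the next paragraph give the spread among genes and not between samples. This interval lay below the 0.5 set in advance for a response across the targets. It does not decide on a p53 response, since levels over background are unknown and targets under background would stay near 0. The largest rises in the list were in plk2.S and plk2.L, at 2.79 ± 0.72 (SE) and 1.90 ± 0.57 (SE). Camera gave this list an unadjusted p of 0.0233 (0.161 with an estimated correlation). The bootstrap interval of its median includes 0 without chordin sample 2 (-0.01 to 0.42). The higher values rested more on chordin sample 1, and without it ccng1.S, ccng1.L, cdkn1a.L, sesn1.L, plk2.S and plk2.L lay at 1.48, 1.06, 0.43, 1.11, 1.73 and 1.15. An effect of the injection cannot be separated from one of chordin in this design.

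The higher values of maternal transcripts in chordin caps were examined for cells from the vegetal side, which could carry vegt. Germ plasm and endoderm transcripts, 29 in all, had a median log2 change of -0.0596 (95% bootstrap interval -0.20 to 0.02), with dazl.L at 0.07, nanos1.L at 0.02 and sox17a.S at -0.89. This does not decide on such cells, since the levels of these transcripts over background are unknown and all 29 are held by the endoderm or the maternal list, whose values had been seen. For the hypothesis of a slower loss of maternal transcripts, 47 other such genes had a median of 0.16 (95% bootstrap interval 0.01 to 0.27), which includes the bound of 0.1, so that slower loss and no such difference cannot be told apart here. The median of the first list was -0.19 without uninjected sample 1, 0.01 without uninjected sample 2, -0.17 without chordin sample 1 and -0.04 without chordin sample 2. That of the second lay between 0.07 and 0.10 with any 1 array left out. Camera gave unadjusted p-values of 0.0102 (lower) for the first and 0.065 (higher) for the second list, and 0.293 and 0.156 with an estimated correlation.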
